A study of Rattus norvegicus with 55 samples.

How the data were processed

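Kidney RNA of 55 rat samples was measured on 1-colour Affymetrix arrays. The values used were the deposited intensities of 8799 probe sets per array, on a linear scale, as the values themselves show. The method and software that summarised probes into probe sets and scaled the arrays are not given in the sources used here. The 2% trimmed mean of the deposited intensities was 500.2 to 500.7 on every array, a ratio of 1.0011 between the highest and the lowest, so the deposited scaling was kept. No pair of arrays held identical values. Arrays were grouped by the stage word in the sample descriptions (immature 13, young 14, mature 14) and 14 arrays whose description has no stage word were kept as a group of their own. The labels do not say that arrays of a group came from separate animals.

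Negative values were set to 0, an offset of 15.82 (a share of 0.1 of the median of all values) was added and log2 was taken, so fold changes are on the log2(intensity + offset) scale and understate the change of dim probe sets. The 59 control probe sets were left out of the tests. Probe sets whose mean log2 value lay below the 25th percentile were removed, which left 6555 probe sets and 3835 named genes. Of all probe sets 7018 carried 1 gene symbol, 308 several and 1473 none in the platform's annotation. Symbols were updated through the gene identifier where the RefSeq gene table of assembly GRCr8 held it (6994 probe sets). A probe set with several symbols was given no name, and a gene was represented by its probe set with the highest mean.

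All 55 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, no covariate), with a moderated F test over the 4 groups and 6 pairwise contrasts, 2-sided. Adjusted p-values are Benjamini-Hochberg values over all probe sets tested, with a threshold of 0.05. The 24 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast, with an estimated correlation and with all probe sets of a gene averaged as alternatives. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The lists cover proximal tubule, thick ascending limb, distal nephron and collecting duct, podocyte, endothelial, smooth muscle and mesangial, immune, erythroid and other tissue markers. They also cover cell cycle, extracellular matrix, the IGF and growth hormone axis, renin-angiotensin-kallikrein genes, eicosanoid and epoxide enzymes, glutathione and xenobiotic enzymes, fatty acid oxidation, amino acid and gluconeogenic enzymes, immediate early and heat shock genes, injury and repair, genes reported in SHR, interferon response, oxidative phosphorylation, ribosomal proteins and the proteasome. The groups, tests, lists and the alternatives of scaling, offset, filter, array weights, prior variance and samples were chosen before the data were examined. So was the rule for named genes. It takes the 10 genes with the largest rise and the 10 with the largest fall past the threshold in each comparison between stage words, and 5 each way in comparisons with the group without a stage word. It adds up to 4 members of each list with the smallest p in mature against immature kidney, and every passing member of the renin-angiotensin-kallikrein, eicosanoid and SHR lists. A planned test of each group mean against 0 was meant for log ratios and was not applicable to intensities.

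The batches were chosen after seeing the data. Ward clustering used 42 control probe sets (bacterial and phage spike-ins, mouse and yeast controls and 5S ribosomal RNA, with none of GAPDH or actin). The tree was cut into 3 batches, a number that was set and not found by the clustering. The batches were used as a block and as separate fits. The block was an additive term, which takes the difference between batches to be the same in every group. Further alternatives chosen after seeing the data left out the 2 arrays with a GAPDH 3'/5' ratio above 3, alone, together with the block and inside batch 3, and each array in turn. Comparisons of a score between groups inside a batch used exact permutation tests.

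The fits were tested on simulated data, in which 67, 67 and 66 of the 6555 probe sets were changed by 0.5, 1 and 2 on the log2 scale. The simulated noise was independent between probe sets and held no batches, so the shares of false calls do not cover batch differences. For mature against immature kidney with all arrays, 35.8%, 92.5% and 100% of these probe sets were recovered, and 11 of 163 calls were false. Inside batch 1 the shares were 8.96%, 43.3% and 86.4%, with 7 of 99 calls false. For the group without a stage word against young kidney inside batch 3 they were 19.4%, 71.6% and 98.5%, with 7 of 133 calls false. Figures were drawn with matplotlib 3.10.9. No background signal per probe set was used here, so signal over background was not analysed.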

Results

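Gene expression in rat kidney was measured on 55 1-colour Affymetrix arrays, each hybridised with total RNA from kidney. Every sample is titled SHR kidney, SHR being the usual short name of the spontaneously hypertensive rat, and every description calls the animals Wistar-derived. The descriptions differ by a stage word, which puts 13 arrays in an immature group, 14 in a young group and 14 in a mature group. A further 14 arrays carry no stage word and form the group without a stage word. Neither ages, sex, diet nor blood pressure stand in the labels, and nothing in them says whether arrays of a group came from separate animals. The p-values therefore measure the spread between these samples, which may be technical. The number of arrays limits the precision of every comparison. The question the labels give is how kidney expression differs between the stages.

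The deposited values were intensities of 8799 probe sets per array. The 2% trimmed mean lay between 500.2 and 500.7 on all 55 arrays and the median value between 136.0 and 183.3. Correlations between arrays on the log2 scale ranged from 0.709 to 0.985, with a median of 0.930. Control probe sets divided the arrays into 3 technical sets, called batches 1, 2 and 3 here, although the labels name no batch. Batch 1 held 6 immature and 4 mature arrays. Batch 2 held 7 immature and 6 young arrays together with 6 arrays without a stage word. Batch 3 held 8 young, 8 without a stage word and 10 mature arrays. The 5S ribosomal RNA control had a median intensity of 43.8 in batch 1, 407.6 in batch 2 and 391.6 in batch 3, and the CreX spike-in control a median of 9891, 7277 and 14926. For 54 of the 55 arrays the most similar array belonged to the same batch, and for 47 it belonged to the same stage group. The probe set that includes 18S ribosomal RNA read 13775 to 20470 on the 7 immature arrays of batch 2 and 17.6 to 1798 on the other 12 arrays of that batch. In batch 3 it read 12858 on replicate 14 without a stage word and 4874 on young replicate 12, against 34.7 to 329.8 on the other arrays there. The GAPDH 3'/5' ratio, a sign of RNA degradation, was 7.18 on mature replicate 1 and 3.47 on mature replicate 9, against 0.827 to 2.62 on the other 53 arrays. The 2.62 was on mature replicate 12, which had an actin 3'/5' ratio of 2.82, and mature replicate 5 had 1.45 and 2.75. Both belong to batch 1, and they stayed in the fits without the 2 arrays of high GAPDH ratio. At an adjusted p of 0.05, 1867 of the 6555 probe sets tested differed somewhere among the 4 groups (moderated F test of limma).

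**Figure D1:**
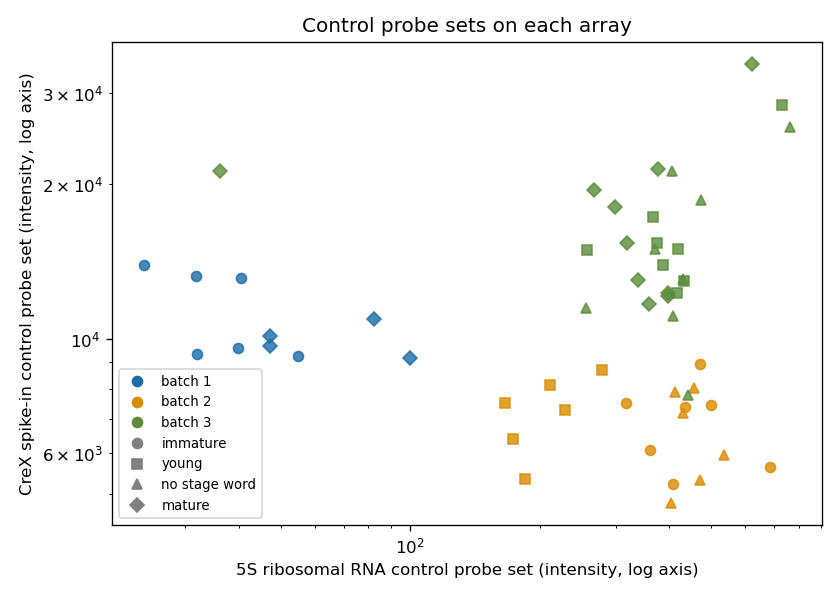
Intensity of the 5S ribosomal RNA control probe set (x axis, log scale) against that of the CreX spike-in control (y axis, log scale) on each of the 55 arrays, 1 point per array, with colour for batch and shape for group. Batch 1 lies at 24.1 to 100 on the x axis and batch 2 at 166.1 to 686.5, while 1 mature array of batch 3 lies at 36.2.

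The widest gap in stage, mature against immature kidney, was led by a rise of Cyp2c11 (probe set J02657_s_at), a cytochrome P450 known from male rat liver. Its mean log2 intensity went from 6.30 ± 1.06 (SD, n = 13) in immature to 11.12 ± 0.74 (SD, n = 14) in mature kidney, a log2 change of 4.81 ± 0.26 (SE) or 28.1-fold (adjusted p = 1.3e-21), and all 14 mature arrays lay above every immature array. The neurofilament gene Nefm (Z12152_at) rose 4.77-fold and Mbl1 (AF080507_at), a mannose-binding lectin, 4.24-fold. Agt (rc_AA943892_at), which encodes angiotensinogen, the precursor of the angiotensins, rose 2.82-fold, and Gc, the vitamin D-binding protein, 2.76-fold. On mature replicates 1 and 9, the 2 arrays of high GAPDH ratio, Agt lay at 10.963 and 10.709 and Mbl1 at 9.984 and 10.555, which adds to both rises. On the other mature arrays Agt lay at 8.56 to 9.81 and Mbl1 at 8.31 to 9.20. Resp18 rose 2.43-fold and Slc22a2, the organic cation transporter of the proximal tubule, 2.41-fold. Jund, Cyb5a and Neurod1 completed the 10 largest rises at 3.12-fold, 2.67-fold and 2.52-fold. The 2 largest falls were in fibrillar collagens. Col1a1 (M27207mRNA_s_at) went from 11.97 ± 0.32 to 9.58 ± 0.54, a log2 change of -2.39 ± 0.16 (adjusted p = 1.1e-17), and all 14 mature arrays lay below every immature array. Col3a1 changed by -2.37 ± 0.22 and Col5a2 by -1.73 ± 0.16, while Col4a5, a basement membrane collagen, changed by -1.67 ± 0.23 and Fn1, fibronectin, by -1.63 ± 0.18. Col3a1 lay at 6.28, 6.44 and 6.92 on mature replicates 1, 9 and 5, whose actin 3'/5' ratios were raised, which adds to its fall. On the other mature arrays it lay at 8.19 to 9.20, among them replicate 12 (8.42), whose ratio was raised too. The other large falls were in Alx1 (-1.96), Rpa3 (-1.79), Irf3 (-1.69), Myl9 (-1.66) and Il15 (-1.65). Other probe sets of a gene did not always go the same way: of 3 others of Fn1 0 were called and 1 went the other way, as did the 2 others of Cyb5a without being called.

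**Figure D2:**
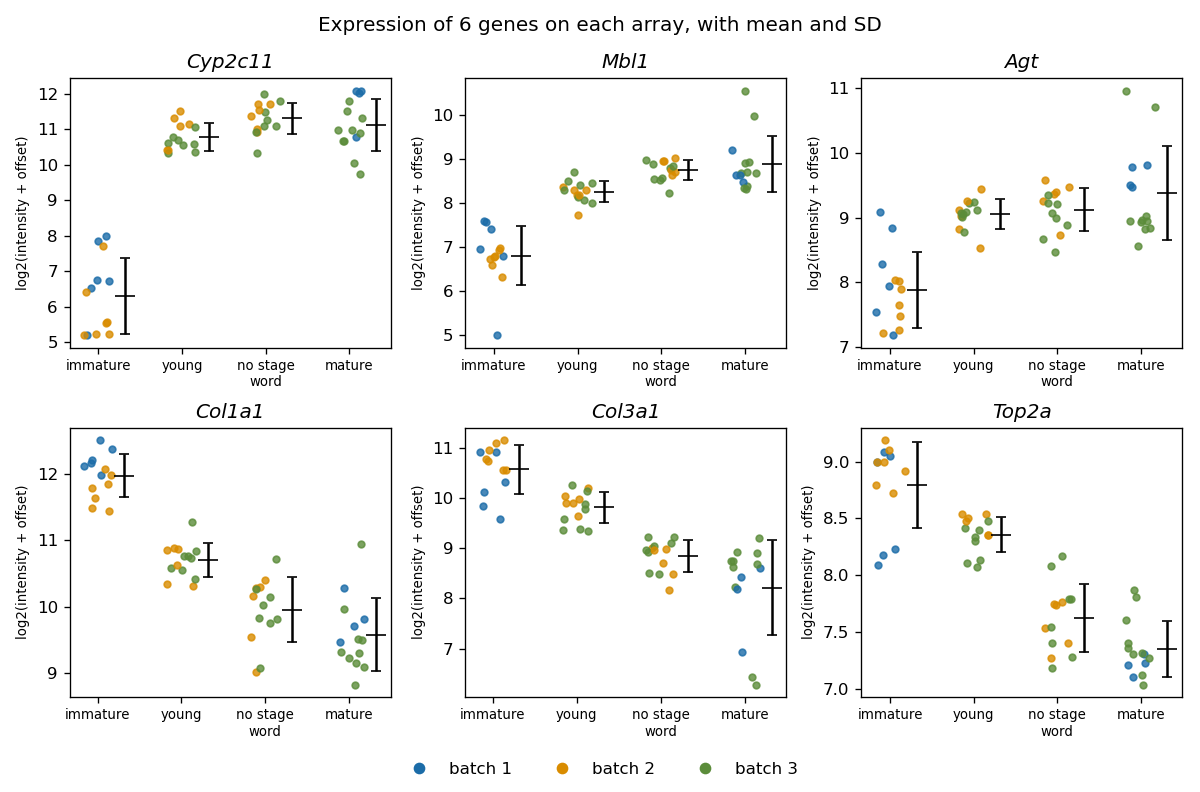
Log2(intensity + offset) of 6 genes on each array (points, coloured by batch) in the 4 groups, with the group mean and SD (black bars) at the right of each group. Cyp2c11 lies at 5.19 to 8.00 on the 13 immature arrays and at 9.73 to 12.10 on the 14 mature arrays, and mean Col1a1 steps down from 11.97 in immature through 10.70 in young and 9.96 without a stage word to 9.58 in mature kidney.

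Among the 24 gene lists fixed beforehand, the extracellular matrix list fell most clearly in mature against immature kidney. Of its 27 measured members 13 fell and 1 rose (14 and 2 adjusted over the list alone), with a median log2 change of -0.28 (camera, adjusted p = 5.1e-07, and adjusted p = 0.014 with an estimated correlation). Beside Col1a1, Col3a1 and Col5a2, the fibrillar collagen gene Col1a2 changed by -1.51 ± 0.14. The cell cycle list had 11 of 23 members lower and 0 higher (11 and 1 adjusted over the list alone, adjusted p = 1.6e-04, and adjusted p = 0.017 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, changed by -1.44 ± 0.16, Top2a, a topoisomerase of dividing cells, by -1.44 ± 0.11 and Cdc20 by -0.69 ± 0.09. Of the 40 ribosomal protein genes 14 were lower, among them Rpl31 (-0.57), Rpl35a (-0.55), Rpl11 (-0.68) and Rps15 (-0.37), and 1 was higher (18 and 1 adjusted over the list alone, adjusted p = 1.7e-04, and adjusted p = 0.051 with an estimated correlation). The proximal tubule list rose, with 10 of 35 members higher and 3 lower (11 and 3 adjusted over the list alone, adjusted p = 0.040, and adjusted p = 0.22 with an estimated correlation). Its examples are transporters, Slc13a3 (0.71 ± 0.13), Slc22a6 (0.66 ± 0.10) and Slc26a1 (0.66 ± 0.12) beside Slc22a2. The eicosanoid and epoxide enzyme list rose as well, with 8 of 21 members higher and 3 lower, also adjusted over the list alone (adjusted p = 0.040, and adjusted p = 0.28 with an estimated correlation). Beside Cyp2c11, its higher members were Pla2g2a (0.95), Cyp2c23 (0.71), Cyp4f6 (0.57), Ptgds (0.53), Ephx1 (0.47), Cyp4f1 (0.42) and Cyp4a8 (0.41), and its lower members were Hpgd (-1.34), which degrades prostaglandins, Alox15 (-1.08) and Pla2g4a (-0.69). Cyp2c23 (0.06, adjusted p = 0.85), Cyp4f6 (adjusted p = 0.20) and Cyp4f1 (adjusted p = 0.16) did not pass with batch as a block, and inside batch 1 Cyp2c23 went the other way (-0.24). Of the ribosomal examples Rpl11 and Rps15 did not pass with the block (adjusted p = 0.10 and 0.22). Another probe set of Top2a, Cyp2c23, Cyp4a8 and Rps15 went the other way without being called.

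The other 19 lists did not pass the camera test in mature against immature kidney over all arrays. In the renin-angiotensin-kallikrein list 3 of 12 members rose, Agt, Ace (0.86 ± 0.16) and Klk1 (0.50 ± 0.16), and Agtr1a, the angiotensin II receptor gene, fell (-0.58 ± 0.13), with the same counts adjusted over the list alone (adjusted p = 0.094). With the block Klk1 did not pass (0.21, adjusted p = 0.42), and inside batch 1 it went the other way (-0.41). In the list of genes reported in SHR 3 of 14 rose and 3 fell on both counts (adjusted p = 0.80), the rises being Srebf1 (0.53), Klk1 and Cyp4a8 and the falls Slc12a1 (-0.82), Agtr1a and Spon1 (-0.49). Of 7 thick ascending limb genes Casr was higher (0.45) and the cotransporter gene Slc12a1 lower, on both counts (adjusted p = 0.69), with Umod at 0.38 and Ppp1r1a at 0.26 not past the threshold. Of 21 genes of the distal nephron and collecting duct 2 were higher and 6 lower on both counts (adjusted p = 0.15), including Calb1, a calcium-binding protein (-1.01 ± 0.13), Aqp3 (-0.58), Fxyd4 (-0.55) and Scnn1g, a sodium channel subunit (-0.52). Of 4 podocyte genes Synpo was higher (0.57) on both counts (adjusted p = 0.49), with Actn4 at 0.47, Ptpro at -0.17 and Wt1 at 0.06 not past the threshold. Of 7 endothelial genes Flt1 was higher (0.49) on both counts (adjusted p = 0.16), with Nos3 at 0.34, Pecam1 at 0.26 and Kdr at 0.24 not past it. Of 11 smooth muscle and mesangial genes Pdgfrb was higher (0.63) and Myl9 and Cald1 (-0.75) lower (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.19), with Myh11 at -0.55 not past it. Of 14 immune genes Cd4 was higher (0.56) and Ccl2 lower (-0.91) on both counts (adjusted p = 0.35), with Cd74 at 0.37 and RT1-Da at 0.23 not past it. Of 4 erythroid genes Hbb (-0.77) and Hbb-b1 (-0.65) were lower on both counts (adjusted p = 0.057), with Alas2 at -0.24 and Hbe1 at -0.11 not past it. Of 13 genes of fat, adrenal, liver and muscle 0 passed on either count (adjusted p = 0.49), with Serpina1 at 0.53, Ckm at 0.47, Lep at 0.26 and Fga at -0.25. The urothelium genes of that list were not among those measured, and Cyp21a1 was its only adrenal gene. Of the members named here as higher or lower, Casr, Synpo, Flt1, Pdgfrb and Cald1 also did not pass with the block.

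Metabolic lists held members that went both ways. Of 36 glutathione and xenobiotic enzymes 8 were higher, among them Gsta1 (0.99) and Gstp1 (0.62), and 4 lower, among them Gsta3 (-1.08) and Ugt8 (-0.70), with 10 and 5 adjusted over the list alone (adjusted p = 0.16, but 0.023 with batch as a block, and there 0.15 with an estimated correlation). Of 30 genes of fatty acid oxidation 3 were higher, including Hadha (0.46), and 4 lower, including Etfa (-1.03), Acox2 (-1.01) and Fabp3 (-0.59), on both counts (adjusted p = 0.33). Of 24 amino acid and gluconeogenic enzymes 2 were higher, including Dao (0.46), and 4 lower, including Gpt (-0.83), Pccb (-0.64) and Pcca (-0.55), on both counts (adjusted p = 0.54). In the IGF and growth hormone list Igfbp5 (1.02), Igfals (0.80) and Igf1r (0.62) were higher and 0 members lower on both counts, with Igfbp3 at -0.42 not past the threshold and another of its probe sets called in the opposite direction. That list had a median of -0.07, a mean of 0.12 and an upward test (adjusted p = 0.38). Of 18 immediate early and heat shock genes 5 were higher, including Jund, Dnajb1 (0.47) and Hsph1 (0.42), and Hspa5 was lower (-0.35), with 7 and 3 adjusted over the list alone. Its median was -0.01, its mean 0.10 and its test upward (adjusted p = 0.54). Of 16 injury and repair genes 3 were higher and 6 lower, including Anxa1 (-1.07), Krt18 (-0.75), Anxa2 (-0.68) and Lgals3 (-0.49), with 4 and 6 adjusted over the list alone (adjusted p = 0.16). Of 12 interferon response genes B2m was higher (0.34) on both counts (adjusted p = 0.46), with Psmb8 at 0.28, Oas1a at 0.26 and Irf1 at -0.21 not past the threshold. Of 53 oxidative phosphorylation genes 2 were higher, including Cox6a2 (0.55), and 8 lower, including Uqcrc2 (-0.80), Ndufc2 (-0.64) and Uqcr11 (-0.50), with 2 and 5 adjusted over the list alone. The median of that list was 0.01 and the mean -0.05 (adjusted p = 0.58, downward). Of 24 proteasome genes Psmd2 was higher (0.59) and Psma2 (-0.76), Psma5 (-0.64) and Psma4 (-0.45) lower on both counts (adjusted p = 0.70). Of the members named here as higher or lower, Hadha, Etfa, Dao, Pccb, Igfbp5, Jund, Hspa5, B2m, Cox6a2, Uqcrc2, Ndufc2, Uqcr11, Psma2 and Psma5 did not pass with the block. Inside batch 1 Hadha (-0.026), Dao (-0.23) and Cox6a2 (-0.27) went the other way.

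Over all probe sets, limma called 1599 between mature and immature kidney, 678 higher and 921 lower. With batch as a block 829 were called, of which 607 were among the 1599, and inside batch 1, which holds 4 mature and 6 immature arrays, 47 were called. Of the 10 largest rises 7 stayed past the threshold with the block, all but Jund, Cyb5a and Neurod1, and of the 10 largest falls 8 did, all but Rpa3 and Irf3. Inside batch 1 the log2 change of Cyp2c11 was 4.91, of Nefm 1.98, of Mbl1 1.85, of Col1a1 -2.40 and of Col3a1 -2.24, while Cyb5a (-0.17) and Neurod1 (-0.18) went the other way. With the block the extracellular matrix list had an adjusted p of 4.3e-13, cell cycle 1.3e-05 and ribosomal proteins 4.9e-05, while proximal tubule (0.087) and eicosanoid enzymes (0.13) no longer passed. Without the 2 mature arrays of high GAPDH ratio the proximal tubule list had an adjusted p of 6.3e-04, and of 0.0056 with the block as well (adjusted p = 0.032 and 0.058 with an estimated correlation). For the eicosanoid list these were 0.019 (adjusted p = 0.28 with an estimated correlation) and 0.099, and it had 0.28 with the probe sets of a gene averaged. Leaving out the 2 arrays also gave upward calls of the glutathione and xenobiotic list (adjusted p = 0.041, and 0.0022 with the block) and the renin-angiotensin-kallikrein list (0.041) and a downward call of the erythroid list (0.048). With the block in addition the amino acid list passed upward (0.027) and the smooth muscle list downward (0.048). With an estimated correlation the adjusted p of these calls was 0.13, 0.066, 0.096, 0.31, 0.15 and 0.14 in this order. With the block and an estimated correlation the adjusted p was 1.1e-04 for extracellular matrix, 0.013 for cell cycle and 0.075 for ribosomal proteins. Inside batch 1 the extracellular matrix (adjusted p = 1.9e-07), cell cycle (adjusted p = 4.9e-04) and ribosomal protein lists (adjusted p = 0.033) shifted downward and the proximal tubule list upward (adjusted p = 0.033). Of their members 24 of 27, 20 of 23 and 29 of 40 had a log2 change below 0 and 22 of 35 one above 0, of which only 5 extracellular matrix and 2 cell cycle members passed the threshold. The eicosanoid list had an adjusted p of 0.48 there. With an estimated correlation inside batch 1 the adjusted p was 0.16 for extracellular matrix, 0.16 for cell cycle, 0.62 for ribosomal proteins and 0.34 for proximal tubule. The high 18S signal lay on 7 of the 13 immature arrays, all of them outside batch 1.

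**Figure D3:**
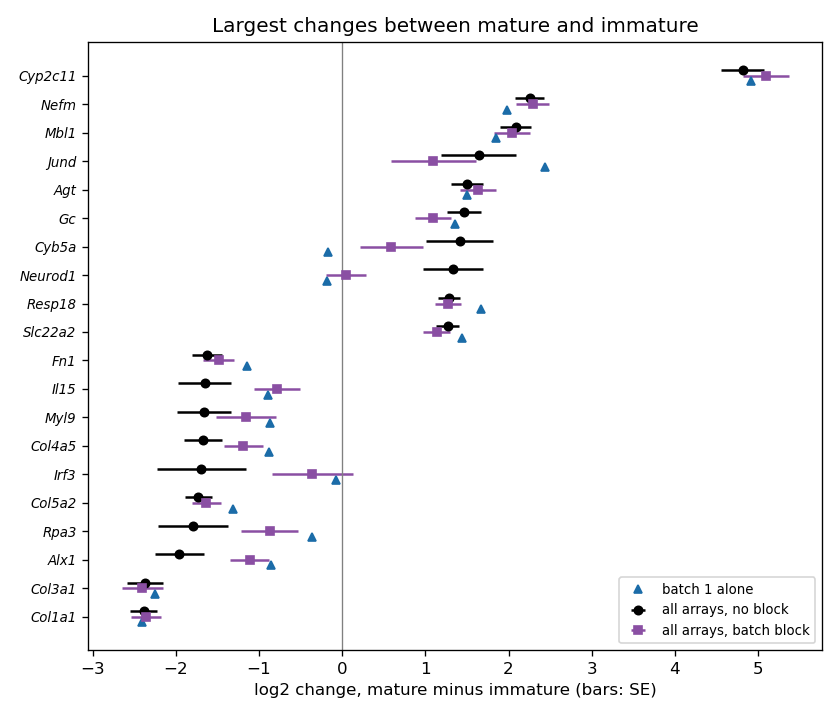
Log2 change from immature to mature kidney (x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis), with circles for all arrays without a block and squares for batch as a block, both with SE as bars, and triangles for batch 1 alone. Cyp2c11 lies at 4.81, 5.09 and 4.91 and Col1a1 at -2.39, -2.36 and -2.40 in these fits, whereas Neurod1 lies at 1.33, 0.05 and -0.18.

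Cyp2c11 also led the rises in young against immature kidney. It was higher by 4.48 ± 0.26 on the log2 scale (22.4-fold, adjusted p = 3.8e-20), with all 14 young arrays above every immature array. Enpep, the aminopeptidase that trims angiotensin II, rose 4.45-fold and Gc 3.56-fold. Tff3, a trefoil factor, rose 3.04-fold, the kinase gene Pdpk1 3.04-fold, Mapk8ip1 2.90-fold, Mbl1 2.74-fold, the protocadherin gene Fat1 2.70-fold, Msn 2.67-fold and Jund 2.58-fold. The largest falls were in Anp32a (-1.78 ± 0.21) and Dbp (-1.39 ± 0.26), a transcription factor driven by the circadian clock, followed by Emc8 (-1.37), the matrix proteoglycan gene Dcn (-1.36), Alx1 (-1.28), Col1a1 (-1.27), Rev1 (-1.22), Nrgn (-1.22), Il15 (-1.20) and Nktr (-1.18). Of the hormone and eicosanoid genes outside these, Agt rose by 1.18, Ace by 0.46, Cyp2c23 by 0.72, Pla2g2a by 0.69, Cyp4a8 by 0.53 and Cyp4f1 by 0.51. Agtr1a changed by -0.50, Cyp4a3 by -0.78, Cyp4a1 by -0.49 and Pla2g4a by -0.45, and of the genes reported in SHR Srebf1 rose by 0.40 and Add1 changed by -0.40. Another probe set of Add1 was called in the opposite direction in this comparison, and other probe sets of Agtr1a and Cyp4a1 went the other way without being called. Of the other probe sets of Anp32a, Dcn and Il15 0 were called. Of these, Cyp2c23, Cyp4a1, Pla2g4a, Srebf1 and Add1 did not pass with batch as a block.

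Of the lists, extracellular matrix fell in young against immature kidney with 9 of 27 members lower and 3 higher (10 and 3 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.24 with an estimated correlation). Cell cycle fell with 5 of 23 lower and 0 higher (6 and 0 adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.22 with an estimated correlation and 0.053 with the probe sets of a gene averaged). Ribosomal proteins fell with 13 of 40 lower and 0 higher (15 and 1 adjusted over the list alone, adjusted p = 7.7e-05, and adjusted p = 0.073 with an estimated correlation). The proximal tubule list rose with 12 of 35 higher and 3 lower (13 and 5 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.18 with an estimated correlation). The other 20 lists did not pass.

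In total 1225 probe sets were called between young and immature kidney, 621 higher and 604 lower. With batch as a block 583 were called, 445 of them among the 1225, and inside batch 2, where the 7 immature arrays carry the high 18S signal, 1921 were called. The rises of Pdpk1, Mapk8ip1, Msn and Jund and the falls of Emc8, Rev1 and Il15 did not pass with the block, and inside batch 2 Pdpk1 went the other way (-0.56). Inside batch 2 Cyp2c11 changed by 5.15, Anp32a by -2.52 and Col1a1 by -1.11. With the block the adjusted p of the lists was 7.1e-05 for extracellular matrix, 0.0025 for cell cycle, 5.6e-07 for ribosomal proteins and 0.21 for proximal tubule, and inside batch 2 it was 0.026, 0.048, 4.3e-10 and 0.69. With an estimated correlation the first 3 of these lists had an adjusted p of 0.046, 0.11 and 0.038 with the block and of 0.51, 0.51 and 0.015 inside batch 2.

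Between young and mature kidney fewer probe sets differed than between either group and immature kidney. Col3a1 changed by -1.60 ± 0.21, Col1a1 by -1.12 ± 0.16, Cdk1 by -1.08 ± 0.16, Top2a by -1.01 ± 0.11 and Col4a5 by -1.01 ± 0.23, and all 14 mature arrays lay below every young array for Top2a (adjusted p = 8.1e-09). The low Col3a1 of mature replicates 1, 9 and 5, given above, adds to the fall of this gene here too. Tfrc, the transferrin receptor gene (-1.29), Idi1, an isoprenoid enzyme (-1.14), Tnfrsf11b (-1.05), Smc4, a condensin subunit (-0.92), and Hmmr (-0.86) were also lower. The rises were led by Pgam2 (1.04 ± 0.25), Nefm (0.99 ± 0.17), Ppp1r16b (0.84), Mfge8 (0.80), Klk1, tissue kallikrein (0.76 ± 0.15), Slc6a6, a taurine transporter (0.75), Acaa1b, a peroxisomal thiolase (0.74), Cyp2e1 (0.74), Rab14 (0.73) and Ptpn6 (0.71), of which another probe set went the other way without being called. Of the eicosanoid list Hpgd was lower (-0.79), which did not pass with batch as a block (adjusted p = 0.22). The extracellular matrix list fell with 7 of 27 members lower and 0 higher (9 and 0 adjusted over the list alone, adjusted p = 1.2e-06, and adjusted p = 0.019 with an estimated correlation). The cell cycle list fell with 3 of 23 lower and 0 higher on both counts (adjusted p = 0.018, and adjusted p = 0.21 with an estimated correlation). The other 22 lists did not pass over all arrays.

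The count for mature against young was 118 probe sets, 40 higher and 78 lower, so that 33.9% were higher, against 43.9% after quantile normalization and 60.5% with each array centred on its median. Without the 2 mature arrays of high GAPDH 3'/5' ratio 59 were called, with batch as a block 86, of which 53 were among the 118, and inside batch 3 29. With the block 6 of the 10 largest rises and 4 of the 10 largest falls (Col3a1, Col1a1, Cdk1 and Top2a) stayed past the threshold. With the block without the 2 arrays 4 of the rises and 4 of the falls did. Inside batch 3 the changes of Col3a1, Col1a1 and Top2a were -1.44, -1.25 and -0.87. The extracellular matrix list had an adjusted p of 1.4e-08 with the block and of 9.0e-07 inside batch 3 (adjusted p = 0.0031 and 0.0076 with an estimated correlation). For the cell cycle list these values were 0.068 and 0.098 (adjusted p = 0.54 and 0.46 with an estimated correlation). Inside batch 3 without the 2 arrays 105 probe sets were called, with an adjusted p of 1.3e-05 for extracellular matrix and 0.0013 for cell cycle (adjusted p = 0.024 and 0.043 with an estimated correlation).

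In mature against young several list calls differed without the 2 arrays of high GAPDH ratio. Without them the cell cycle list had an adjusted p of 3.6e-05, and of 0.0012 with the block as well (adjusted p = 0.0031 and 0.040 with an estimated correlation). The fatty acid oxidation list had 0.96 with all arrays, 0.14 with the block and 0.12 without the 2 arrays, but passed upward with both (adjusted p = 1.2e-05, and 0.0074 with an estimated correlation). It also passed inside batch 3 without the 2 arrays (adjusted p = 1.8e-05, and 0.023 with an estimated correlation), where 24 of 30 members had a log2 change above 0 and 2 passed the threshold. In the same 2 fits the amino acid list had 0.0012 and 1.5e-04 (adjusted p = 0.045 and 0.052 with an estimated correlation) and the glutathione and xenobiotic list 0.0071 and 0.0013 (adjusted p = 0.11 and 0.15 with an estimated correlation), both upward. The renin-angiotensin-kallikrein list passed upward without the 2 arrays (adjusted p = 0.045, and 0.11 with an estimated correlation) and inside batch 3 without them (adjusted p = 0.017, and 0.043 with an estimated correlation). Upward calls that an estimated correlation ended were those of proximal tubule (adjusted p = 0.021, then 0.11), ribosomal proteins (0.021, then 0.32) and proteasome (0.0086, then 0.21) with the block without the 2 arrays. The same held for proteasome (0.036, then 0.46) and the glutathione list (0.047, then 0.18) without the 2 arrays, and for immune genes inside batch 3 without them (0.031, then 0.21).

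The group without a stage word differed from mature and young kidney in 27 and 15 probe sets. Against immature kidney 1773 probe sets were called, 831 higher and 942 lower, with the largest rises in Cyp2c11 (5.01 ± 0.26, 32.2-fold), Pdpk1 (2.28), Mbl1 (1.94), Gc (1.86) and Enpep (1.76) and the largest falls in Irf3 (-2.36), Col1a1 (-2.02), Rpa3 (-1.98), Nktr (-1.85) and Egfl7 (-1.84). The extracellular matrix list fell with 13 of 27 lower and 3 higher (14 and 4 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation), and the cell cycle list with 10 of 23 lower and 0 higher on both counts (adjusted p = 9.6e-04, and adjusted p = 0.059 with an estimated correlation). Ribosomal proteins fell with 13 of 40 lower and 2 higher (15 and 4 adjusted over the list alone, adjusted p = 0.0073, and adjusted p = 0.19 with an estimated correlation), and the proximal tubule list rose with 11 of 35 higher and 4 lower (13 and 4 adjusted over the list alone, adjusted p = 0.0093, and adjusted p = 0.15 with an estimated correlation). With batch as a block 1313 were called and inside batch 2 2848, and the rise of Enpep did not pass with the block. The lists then had an adjusted p of 2.4e-05 for extracellular matrix, 3.5e-05 for cell cycle, 0.0017 for ribosomal proteins and 0.18 for proximal tubule, and inside batch 2 of 0.0053, 0.022, 0.15 and 0.27. With an estimated correlation the adjusted p with the block was 0.023 for extracellular matrix, 0.023 for cell cycle and 0.19 for ribosomal proteins, and inside batch 2 it was 0.26 for both extracellular matrix and cell cycle. Inside batch 2 the immune and the glutathione and xenobiotic lists passed upward (adjusted p = 0.042 for both, and 0.26 with an estimated correlation), and with the block without the 2 arrays the fatty acid oxidation list passed downward (adjusted p = 0.043, and 0.18 with an estimated correlation).

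Against young kidney the group without a stage word was lower in Smc4 (-0.98), Col3a1 (-0.97 ± 0.21), Eif5, a translation initiation factor (-0.90), Col1a1 (-0.75 ± 0.16) and Top2a (-0.74 ± 0.11), and higher in Dnase1 (0.63), the cathepsin gene Ctss (0.54) and Slc6a13, a transporter of GABA and taurine (0.52). Of the other probe sets of Col3a1, Col1a1, Eif5, Top2a and Dnase1, all of which went the same way, 0 were called. Only 15 probe sets were called, 4 higher and 11 lower, so that 26.7% were higher. With each array centred on its median only 3 were called, 66.7% of them higher, too few to compare the shares. The cell cycle list fell with 3 of 23 lower and 0 higher on both counts (adjusted p = 0.0037, and adjusted p = 0.059 with an estimated correlation) and the extracellular matrix list with 2 of 27 lower and 0 higher on both counts (adjusted p = 0.0071, and adjusted p = 0.23 with an estimated correlation). The immune list shifted upward with 0 of 14 members called, 2 adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.059 with an estimated correlation). With batch as a block 66 were called, inside batch 2 1778 and inside batch 3 0, where 187 had an unadjusted p under 0.05. Without the 2 mature arrays of high GAPDH ratio, which enter through the shared spread, 33 were called. The adjusted p of the cell cycle, extracellular matrix and immune lists was 0.0036, 0.013 and 0.013 with the block, 0.23, 0.077 and 0.16 inside batch 2 and 9.8e-04, 0.28 and 0.012 inside batch 3. With an estimated correlation the adjusted p of these lists was 0.11, 0.30 and 0.067 with the block, and inside batch 3 it was 0.098 for cell cycle and 0.034 for immune genes. Inside batch 3 without the 2 arrays cell cycle had 0.0034 and immune genes 0.0033, but an adjusted p of 0.12 each with an estimated correlation. The ribosomal protein list passed upward inside batch 2 (adjusted p = 0.0018, and 0.53 with an estimated correlation).

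Mature kidney was lower than the group without a stage word in Myl9, a myosin light chain (-1.29 ± 0.32), Dnase1 (-0.81 ± 0.15), Ly6c (-0.68), the water channel gene Aqp2 (-0.55 ± 0.11) and Cux1 (-0.54), and higher in Ppp1r16b (0.79 ± 0.19), Abat (0.62), which degrades GABA, Cacna1c (0.51), Rab3ip (0.50) and Patj (0.48). Another probe set of Myl9, Abat and Cacna1c went the other way without being called. In all 27 probe sets were called, 13 higher and 14 lower, so that 48.1% were higher, against 36.6% of 41 after quantile normalization and 26.7% of 15 with each array centred on its median. The extracellular matrix list shifted downward with 0 of 27 members called on either count (adjusted p = 0.0073, and adjusted p = 0.38 with an estimated correlation), with an adjusted p of 0.015 under the block and 9.0e-04 inside batch 3 (adjusted p = 0.40 and 0.070 with an estimated correlation). Inside batch 3 without the 2 arrays of high GAPDH ratio the list had an adjusted p of 0.018 (0.28 with an estimated correlation) and 218 probe sets were called, while with the block without these arrays it did not pass (adjusted p = 0.17). The fatty acid oxidation list had 0.43 with all arrays but shifted upward with the block (adjusted p = 0.015) and inside batch 3 (0.041), without the 2 arrays (6.1e-04), with the block without them (3.4e-06) and inside batch 3 without them (7.6e-07). With an estimated correlation the adjusted p was 0.40, 0.46, 0.13, 0.0031 and 0.0069, and in the last of these fits 23 of 30 members had a log2 change above 0 and 5 passed. Inside batch 3 without the 2 arrays the amino acid (adjusted p = 6.9e-05) and glutathione lists (0.033) shifted upward too (adjusted p = 0.11 and 0.37 with an estimated correlation). The distal nephron list passed downward only with the probe sets of a gene averaged (adjusted p = 0.019). With batch as a block 345 were called, the 27 among them, and inside batch 3 14.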

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

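The random regroupings of arrays were planned, and all other tests in this part were chosen after the result was seen. The deposited labels name no batch, and the technical sets of arrays used here come from the control probe sets.

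The change between young kidney and the group without a stage word differed between batches 2 and 3 in 464 probe sets by a limma interaction test. The lowest level of the probe set that includes 18S ribosomal RNA on the 7 immature arrays of batch 2 was 13775, while the other 48 arrays had a median of 118.4 and a highest value of 12858. The GAPDH 3'/5' ratio was 7.18 on mature replicate 1 and 3.47 on mature replicate 9, against a highest value of 2.62 elsewhere. The probe sets behind this ratio are controls outside the tests, and the ratio served to choose the 2 arrays left out in some alternatives.

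Many more probe sets were called against immature kidney (1599 for mature, 1225 for young) than between mature and young kidney (118). The control-probe batch alone does not give every call, because 47 probe sets were called between mature and immature kidney inside batch 1. Of these 47, 43 had the same direction between young and immature kidney inside batch 2. Whether batch gives the unequal counts cannot be decided, since no batch holds immature, young and mature arrays together. Inside batch 3, 29 were called between mature and young kidney, and 105 without the 2 arrays of high GAPDH ratio. Processing inside batch 2 may account for part of the 1921 probe sets called there between young and immature kidney. Of those, 568 of 1096 higher and 538 of 825 lower ones went the same way between mature and immature kidney in batch 1. That is another stage contrast, so these shares alone do not tell processing from stage for these probe sets. A score over these probe sets was -0.04 ± 0.39 (SD, n = 4) in mature and -0.30 ± 0.16 (SD, n = 6) in immature kidney of batch 1 (exact permutation p = 0.171, 2-sided, adjusted p = 0.403 over 4 comparisons), so processing and stage cannot be told apart for them with so few arrays. A difference in stage stays open beside it, as does the unequal share of arrays parted at RT1-Bb.

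The extracellular matrix list fell from immature and from young to mature kidney. Ribosomal RNA signal on the 7 immature arrays of batch 2 was not needed for the fall from immature kidney, since inside batch 1, which holds none of them, the unadjusted camera p was 8.1e-09 (adjusted p = 0.16 with an estimated correlation, against 4.3e-13 to 0.017 over the alternatives on all batches). RNA quality was unequal inside batch 1, though. Mature replicates 5 and 12 had actin 3'/5' ratios of 2.75 and 2.82, against 0.869 to 1.81 on the immature arrays there. Its part in the fall inside batch 1 was not tested. For the fall from young kidney, degraded RNA on 2 mature arrays is argued against by an adjusted p of 4.8e-09 without them. Control-probe batch is argued against by 1.4e-08 with the block and 9.0e-07 inside batch 3, in a range of 4.8e-09 to 0.024 over the alternatives. The block takes batches to differ equally in all groups, which the interaction test went against for 464 probe sets. The fit inside batch 3 does not rest on this. As a hypothesis, the fall may follow the stage, although sampling of the kidney, sex and diet were not tested.

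The contrast of the group without a stage word with young kidney called 1778 probe sets inside batch 2 and 0 inside batch 3 (limma, 187 at an unadjusted p under 0.05, and 5 called there without the 2 mature arrays of high GAPDH ratio). A stage difference shared by both batches does not account for this, given the 464 probe sets of the interaction test and a correlation of 0.077 across probe sets between the changes, where genes are not independent replicates. The clearest were Vegfa (-1.76 in batch 2, -0.20 in batch 3) and Pdpk1 (1.56 and 0.01), named after their values were seen. A further processing split inside batch 2 is a candidate explanation: 19 probe sets part its 13 immature and young arrays from the 42 others, against at most 1 sharing any partition in 100 shuffles. Each probe set was shuffled on its own, which removes all correlation between probe sets. The shuffles therefore show only that the 19 vary together, and probe sets of Vegfa, named above, are among them. Stage alone does not give that partition, since the 42 include immature arrays of batch 1 and young arrays of batch 3, and whether the processing or the animals of the 13 arrays differed stays open.

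The real counts were set against 100 splits of the arrays for each comparison, the real split included, drawn without regard to the batches. For any difference among the 4 groups 1 split, the real one, reached 1867 probe sets and the highest other 15. The real split was also the 1 largest for mature against immature (1599, highest other 1308), young against immature (1225, 13), mature against young (118, 4) and the group without a stage word against immature (1773, 95). For mature kidney against the group without a stage word 4 splits reached the real 27, the highest at 752, and for that group against young kidney 4 reached 15, the highest at 362. The highest of 1308, 752 and 362 point to a structure of the samples, so that for these 3 comparisons the splits alone do not settle whether chance is excluded. For the other 4 results no other split drawn reached the real count. The splits ignored the batches, over which the groups are unevenly spread, so they cannot tell stage from batch. Whether the splits that gave 1308, 752 and 362 follow the batches was not tested. Splits by batch inside 1 group called 2918 probe sets in immature kidney (batch 2 against 1), 2068 in young kidney and 2499 in the group without a stage word (both batch 3 against 2). Inside mature kidney 256 were called (batch 3 against 1). Apart from mature kidney, these counts exceed the 1867 of any difference among the 4 groups. They are partly confounded with the partition of arrays at RT1-Bb, described below. Of its smaller set, immature and mature kidney each had 3 arrays in batch 1, against 0 in batch 2 and 0 in batch 3. Young kidney and the group without a stage word each had 3 in batch 2 and 0 in batch 3. With batch as a block mature against immature, mature against the group without a stage word and that group against young called 829, 345 and 66.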

How the results depend on the processing

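The alternatives with batch as a block, inside 1 batch, without the 2 arrays of high GAPDH ratio and without each array in turn were chosen after the result was seen, and the others were planned. No paired analysis was possible because the replicate numbers only name arrays and pair none. The test of group means against 0 was not run, since the values are no log ratios. Of 194 named gene results, 184 kept direction and side of the threshold under quantile normalization, 176 with arrays centred on the median, 194 with a trended and robust prior, 134 with the batch block and 171 without the 2 arrays. Of the results that could be fitted there, 24 of 113 kept both inside batch 1 (75 were weaker and 14 reversed), 44 of 50 inside batch 2 and 8 of 39 inside batch 3 (31 weaker). The named genes of mature against immature kidney include some that had not passed with all arrays. For these, staying short of the threshold in the same direction counts as kept. The 24 and the counts out of 194 therefore exceed the number of results that stayed past the threshold. Of the 19 gene list shifts 3 held with an estimated correlation, the extracellular matrix and cell cycle lists in mature against immature and the extracellular matrix list in mature against young. With the batch block 16 shifts were called, without the 2 arrays 26 and with both changes 27. Fits to 1 batch hold fewer arrays, and for all other changes the cause was not tested.

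With array weights 3984 probe sets were called for any difference among the 4 groups, 3691 for mature against immature, 2902 for young against immature, 260 for mature against young, 73 for mature against the group without a stage word, 3831 for that group against immature and 372 for it against young. With the batch block mature against immature gave 829, young against immature 583, mature against the group without a stage word 345 and that group against young 66. Block and leaving out the 2 arrays together gave 851 and 251 for the last 2. Inside batch 1 mature against immature gave 47. Inside batch 2 young against immature gave 1921, the group without a stage word against immature 2848 and against young 1778. Inside batch 3 mature against young gave 29, mature against the group without a stage word 14, and that group against young 0 (limma, 187 at an unadjusted p under 0.05), and without the 2 arrays of high GAPDH ratio 105, 218 and 5. Mature against young gave 55 without the 2 young arrays numbered 30 and 43, 59 without the 2 arrays of high GAPDH ratio and 50 with only the 2 groups compared. Mature against the group without a stage word gave 41 after quantile normalization, 15 with arrays centred, 14 with no filter, 44 with the filter at the median, 17 without arrays 30 and 43 and 8 with only the 2 groups. The group without a stage word against young gave 3 with arrays centred, 8 without arrays 30 and 43, 33 without the 2 arrays of high GAPDH ratio and 76 with only the 2 groups.

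Leaving out each array in turn gave 1696 to 1990 for any difference, 1371 to 1793 for mature against immature, 1032 to 1407 for young against immature and 1546 to 1962 for the group without a stage word against immature. Mature against young ranged from 61 to 160 around 118. It gave 67, 63, 63, 61, 64 and 73 without young replicates 1, 2, 3, 4, 13 and 14, and 72, 66 and 62 without mature replicates 1, 5 and 9. Mature against the group without a stage word ranged from 13 to 50 around 27. It gave 13, 16 and 17 without replicates 1, 4 and 8 of that group, 17, 15 and 17 without mature replicates 1, 5 and 9, and 46, 47, 48 and 50 without mature replicates 3, 6, 10 and 13. The group without a stage word against young ranged from 8 to 23 around 15. It gave 9 and 8 without its replicates 2 and 9, 9 without young replicate 3 and 23 without mature replicate 9.

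Reversed log2 changes in mature against immature inside batch 1 were those of Cox6a2 (-0.27), Cyb5a (-0.17), Cyp2c23 (-0.24), Dao (-0.23), Hadha (-0.026), Klk1 (-0.41), Lep (-0.23), Neurod1 (-0.18), Oas1a (-0.016), Pecam1 (-0.12), Psmb8 (-0.12), RT1-Da (-0.13), Umod (-0.39) and Wt1 (-0.99). With the block they were Igfbp3 (0.025), Kdr (-0.086), Pecam1 (-0.065), Psmb8 (-0.074), Umod (-0.11) and Wt1 (-0.22). With the block and without the 2 arrays they were Igfbp3 (0.056), Kdr (-0.14), Lep (-0.0081), Psmb8 (-0.050), Umod (-0.011) and Wt1 (-0.35). Wt1 reversed without the 2 arrays alone (-0.15), and Hbe1 (0.041) and Ppp1r1a (-0.028) with array weights. In young against immature Pdpk1 reversed inside batch 2 (-0.56) and with the block without the 2 arrays (-0.063). Of these, Cox6a2, Cyb5a, Cyp2c23, Dao, Hadha, Klk1, Neurod1 and Pdpk1 had passed the threshold with all arrays.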

Other observations

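All tests in this part were chosen after the result was seen. The genes named here were also chosen after their values were seen.

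Inside batch 3, where 8 young, 8 arrays without a stage word and 10 mature arrays stand side by side, the list of 4 erythroid genes shifted downward from young to mature kidney (camera, adjusted p = 1.1e-04, and 0.039 with an estimated correlation), with 2 members past the threshold. It also shifted downward from young kidney to the group without a stage word (adjusted p = 5.5e-08, and 0.0047 with an estimated correlation), where limma called 0 members and 0 probe sets in all (187 at an unadjusted p under 0.05). The oxidative phosphorylation list, genes of the respiratory chain, shifted upward in mature kidney against the group without a stage word (adjusted p = 1.7e-05, and 0.041 with an estimated correlation) and downward in that group against young kidney (adjusted p = 1.7e-05, and 0.026 with an estimated correlation). In each case 42 of 53 members had a log2 change of that sign and 0 passed the threshold. The fatty acid oxidation list shifted upward in mature kidney against the group without a stage word as well (adjusted p = 0.041, and 0.46 with an estimated correlation), and without the 2 arrays of high GAPDH ratio it had 7.6e-07 there (0.0069 with an estimated correlation).

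The erythroid and oxidative phosphorylation lists did not pass in the same contrasts over all arrays. The fatty acid oxidation list did not pass over all arrays without a block but passed with it, as given above. Mature against the group without a stage word gave the oxidative phosphorylation list an adjusted p of 0.64 with all arrays, 0.075 with batch as a block (0.47 with an estimated correlation) and 0.61 without the 2 arrays of high GAPDH ratio. The group without a stage word against young kidney gave it 0.45, 0.41 and 0.42, and gave the erythroid list 0.41, 0.40 and 0.42. Mature against young kidney gave the erythroid list 0.44, 0.10 and 0.16, and 0.021 with the block and without the 2 arrays together (adjusted p = 0.21 with an estimated correlation). Both of those arrays lie in batch 3, and inside batch 3 without them the oxidative phosphorylation list had an adjusted p of 7.6e-07 in mature kidney against the group without a stage word and 4.5e-06 in that group against young kidney (adjusted p = 0.16 for both with an estimated correlation). The erythroid list had 2.5e-05 there in mature against young kidney and 1.4e-06 in the group without a stage word against young kidney (adjusted p = 0.024 and 0.018 with an estimated correlation). Inside batch 2 the group without a stage word against young kidney gave 4 of 4 erythroid genes (median 0.26) and 28 of 53 oxidative phosphorylation genes with a log2 change above 0 (adjusted p = 0.23 for both lists).

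The major histocompatibility gene RT1-Bb (probe set X56596_at) lay at 10.48 to 11.23 on 12 arrays and at 6.58 to 8.12 on the other 43 on the log2 scale. Its other probe set with the same partition, U65217_i_at, went the opposite way, at 4.06 to 5.30 on the 12 arrays and 7.57 to 9.80 on the 43, so these values do not give a direction for the level of the gene. The 12 arrays were 3 of each group, namely immature replicates 1, 2 and 3, young 1, 2 and 14, mature 4, 8 and 12, and replicates 4, 8 and 12 without a stage word, and 0 of them lay in batch 3. Inside batches they were not balanced, with 0 of 7 immature, 3 of 6 young and 3 of 6 arrays without a stage word in batch 2, and 3 of 6 immature and 3 of 4 mature arrays in batch 1. The contrasts with immature kidney inside batch 2 (1921 and 2848 probe sets called) and batch 1 (47) are therefore partly confounded with this partition. So are the splits by batch inside 1 group and the batch block, since the 12 arrays are unevenly spread over the batches. Rats of more than 1 stock may explain this: 9 probe sets, among them RT1-Ba, RT1-Db1, Cela1, Ptprj and Cyfip2, had their widest gap between the same arrays, against at most 1 sharing any partition in 100 shuffles. Each probe set was shuffled on its own, so any structure that probe sets share would exceed this, and both probe sets of RT1-Bb are among the 9. More than 1 stock stays a hypothesis, since it was found and tested on the same arrays.

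Between young and immature kidney inside batch 2, 5 of 9 measured circadian clock genes passed the threshold, Bmal1 higher (0.59) and Dbp (-1.65), Nr1d2 (-0.87), Per2 (-0.56) and Bhlhe40 (-0.22) lower, where 1921 of all 6555 probe sets passed. Over all arrays Bmal1 (0.19, adjusted p = 0.56) and Bhlhe40 (-0.07, adjusted p = 0.71) did not pass, while Dbp (-1.39), Nr1d2 (-0.80), Per2 (-1.07) and Tef, in the other direction (0.31, adjusted p = 0.049), did. Under the batch block Tef had a log2 change of 0.08 (adjusted p = 0.75). A different time of day of collection could give this, and of Nr1d1, Tef and Hlf, which were not used to notice it, 0 were lower past the threshold (limma, log2 changes of -0.04, 0.19 and 0.06, of which 1 was below 0). Time of day and stage cannot be told apart, because the labels give no time and these genes could peak at other hours.

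Whether the group without a stage word lies between young and mature kidney was not settled. In batch 3 a score over the probe sets called in batch 2 was 0.32 ± 0.14 (SD, n = 8) in it, 0.23 ± 0.19 (SD, n = 8) in young and 0.21 ± 0.23 (SD, n = 10) in mature kidney. The exact permutation p against young was 0.302 (2-sided, adjusted p = 0.403 over 4 comparisons), and mature against young had an exact permutation p of 0.834. A score built from young against immature kidney that does not part young from mature kidney cannot place a group between them, so the place of the group stays open. The mature mean depends on the 2 arrays of high GAPDH ratio: without them mature minus young turned from -0.02 to 0.07 (exact permutation p = 0.374, n = 8), and mature minus the group without a stage word went from -0.11 to -0.02 (exact permutation p = 0.787).

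Ephx2 (probe set X60328_at) ranged from 4.81 to 9.60 on the log2 scale, with 14 arrays above and 41 below its widest gap of 0.71.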
